A study of Homo sapiens with 4 samples.

How the data were processed

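Total RNA of HT29 cells was sequenced in 4 libraries: 2 of untreated cells and 2 of cells treated with 100 µM fluorouracil for 2 h, per the labels. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No vehicle is named for the untreated cells.

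The authors deposited a table of 33117 rows with a gene symbol and an FPKM value for each library. The submitters' processing notes name TopHat2 2.1.0, an aligner, and Cufflinks 2.2.1, which estimates FPKM, together with the builds hg38 and mm10, without saying which was used for what. The symbols are human. The annotation and any scaling between libraries are not given in the sources used here. FPKM divides by transcript length and by the library total, so a change in a few abundant transcripts or in the length model moves other values. The deposited FPKM of fluorouracil replicate 2 carry a median of 6 significant digits, those of the other 3 libraries 16.

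The number of fragments per library is unknown, so no counting interval was computed. Low values gave the relative depth of 3 libraries, because whole fragments over the same lengths give fixed ratios between libraries. Among rows below 0.5 FPKM in both libraries, 18.5% shared 1 ratio between the untreated libraries, within 0.1%, and that ratio makes untreated replicate 2 1.05 times as deep as replicate 1. For fluorouracil replicate 1, 19.0% of such rows shared a ratio that makes it 1.02 times as deep as untreated replicate 1. For fluorouracil replicate 2, the most frequent ratio held 0.289% of 2418 rows, and no relative depth was derived.

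The table has 28 rows with a date-like number in place of a symbol, which were left out, and 3101 rows for further loci of a symbol, of which 3 were among the tested genes. In fluorouracil replicate 2, a block of 78 rows from MFRP to MICALL2 followed the other libraries better after a shift by 1 row (r of 0.917 across the rows, against 0.412 in place). None of 285 other blocks of that length did so. These rows were kept in the main analysis, no gene named here lies in the block, and the analysis was repeated without it.

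Values were transformed to log2(FPKM + 0.1). Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 12462 in all. Fluorouracil was compared with untreated cells by limma 3.58.1 in R 4.3.3 with a trended prior variance, two-sided, on 2 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera on the same values, with a preset inter-gene correlation of 0.01, an estimated correlation as an alternative, and fry as a self-contained test. Of 28 lists fixed before the data were examined, 25 had at least 5 tested members, and adjustment ran over these. A list or gene is described as higher or lower by range when both treated values lie above, or below, both untreated values; chance gives 33.3% for the directions together.

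Genes named in the report were chosen by a rule fixed before the data were examined. It takes SHH, FOS, EGR1, JUN, MYC and TYMS whatever their result, and any immediate early or Hedgehog pathway gene that passed. It adds the 12 largest changes in each direction among genes that passed. As none passed, these places were filled by the smallest unadjusted p among genes with non-overlapping groups. For each other called list it takes the 4 members with the smallest p in the direction of the list, of which the text gives examples; some genes chosen by the rule are not reported here. The other Hedgehog and immediate early genes, and other genes outside the rule, were chosen after their values were seen.

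Symbols were matched to GENCODE 29 on GRCh38 for position, type, transcript length and GC content, through older symbols where needed. Of all rows, 22808 matched by symbol, 2139 by a synonym and 25 by a newer or older symbol, while 5016 did not match. Small RNA and tRNA rows are those not protein-coding with such an annotated type or a symbol of that form. Genome positions are those of this annotation, and the table itself has none. The GC and length trend was removed by a loess fit (span 0.3) of each library's deviation from the mean of the 4 libraries, over 10957 protein-coding genes.

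Both steps were tested on simulated data with 200 of 12462 genes changed, in 10 runs per fold size, for the comparison of fluorouracil with untreated cells. When all libraries were as alike as the untreated pair, limma recovered on average 88.8% of genes changed 4-fold. When 1 treated library deviated as far as fluorouracil replicate 2, it recovered 0% of genes changed 4-fold and on average 6.90% of genes changed 16-fold. In all 10 runs at each fold size, camera called a list of 30 raised genes at an unadjusted p below 0.05. It also called a list of 30 unchanged genes in 1 of 10 runs with alike libraries at 2-fold and in 1 of 10 with a deviating library at 16-fold, and in 0 of 10 in each of the other 4 settings. In these runs list members were picked at random, and each deviation was drawn from a random gene of like expression. Deviations shared by genes of like GC content or length were therefore not kept. The runs cannot show how often camera calls real lists whose unchanged genes deviate together. All 30 raised genes were changed by the same fold, 2-fold or more. Lists with smaller mean changes, as most called lists had, were not covered. Unchanged genes called by limma averaged 1.70 to 4.30 per run with alike libraries and 0 with a deviating one.

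The alternatives were other pseudocounts, other filters on low values, quantile normalization, median-ratio scaling, a block for the replicate number, limma without the trend and leaving out each library in turn. Chosen after seeing the data were the restriction to protein-coding genes, the removal of the GC and length trend, and the removal of the shifted block. Scripts ran in Python 3.11.15 and R, and figures were drawn with matplotlib 3.10.9.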

Results

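RNA was sequenced from HT29 cells, an established human colorectal adenocarcinoma line, left untreated or kept with 100 µM fluorouracil for 2 h. Fluorouracil is a pyrimidine analogue used as chemotherapy in colorectal cancer; its metabolites inhibit thymidylate synthase and enter RNA. Each condition was represented by 2 libraries, and each library by 1 value per gene in FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library. The title of the study names the Hedgehog ligand gene SHH, the immediate early genes and chemotherapy, so the comparison of fluorouracil with untreated cells asks how these transcripts responded to the drug. Values after ± are the SD of 2 libraries (n = 2). Log2 changes refer to FPKM plus a pseudocount of 0.1 and understate the change of weakly expressed genes. The FPKM summed to 434628 and 427007 in untreated replicates 1 and 2, to 440558 in fluorouracil replicate 1 and to 764861 in fluorouracil replicate 2.

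SHH, which encodes the secreted ligand Sonic hedgehog, had lower FPKM in both treated libraries than in both untreated ones. It measured 8.97 and 7.04 FPKM in the untreated libraries and 4.08 and 3.08 in the treated ones. The group values were 8.01 ± 1.37 and 3.58 ± 0.709 FPKM. The log2 change was -1.14 (SE 0.33), with a limma p of 0.0235 before and 0.671 after adjustment over 12462 genes, so SHH did not pass the test. SHH lies on the minus strand of chromosome 7, from 155799986 to 155812273 (GRCh38).

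The Hedgehog pathway list as a whole was not called. Of its 18 genes, 7 reached a mean of 1 FPKM; 2 had non-overlapping higher values, 2 non-overlapping lower values, and 3 overlapped. Their mean log2 change was -0.11 (camera adjusted p = 0.498). With the GC and length trend of the libraries removed, the mean was -0.36 (adjusted p = 0.235), and the median of fluorouracil replicate 2 went from 0.10 to -0.92. The mean was -0.03 without untreated replicate 1 (adjusted p = 0.579) and -0.19 without untreated replicate 2 (adjusted p = 0.421). The other gene with lower values was PTCH1, which encodes the receptor of the ligand, at 1.87 and 1.71 FPKM untreated and 1.41 and 0.749 FPKM treated. SUFU, which encodes a negative regulator of the GLI transcription factors, was at 1.20 and 1.26 FPKM untreated and 2.70 and 3.34 FPKM treated. GLI1, a transcriptional target of the pathway, had 0.223 to 0.424 FPKM in the 4 libraries, and SMO, the signal transducer, was listed at 0 in all 4.

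The immediate early genes, a class of transcription factors and signalling regulators that respond to stimuli without new protein synthesis, rose as a group. Of 30 tested members, 23 had higher values in both treated libraries than in either untreated one, 4 had lower values and 3 overlapped. The mean log2 change was 1.07 (camera adjusted p = 2.62e-08 with the preset correlation; adjusted p = 0.604 with an estimated correlation). The median was 0.77 in fluorouracil replicate 1 and 1.31 in fluorouracil replicate 2; with the GC and length trend of the libraries removed, these medians were 0.76 and 0.36. By limma, 16 members had an unadjusted p below 0.05 in either direction, among them MYC and KLF6, which had lower treated values. When adjusted over the list alone 11 passed, again with MYC and KLF6 among them, and 0 passed when adjusted over all genes tested. Immediate early genes are named in the study's title, and the list was not taken from these libraries.

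EGR1, a zinc finger transcription factor, measured 9.54 and 6.53 FPKM in the untreated libraries and 59.7 and 68.0 FPKM in the treated ones. Its log2 change was 2.90 in fluorouracil replicate 1 and 3.09 in replicate 2. FOS, a subunit of the AP-1 transcription factor, was at 8.20 ± 0.353 FPKM untreated and 20.5 ± 1.62 FPKM treated, a log2 change of 1.31 (SE 0.27). JUN, its dimerization partner, was at 20.4 ± 1.14 and 50.1 ± 0.389 FPKM (log2 change 1.29, SE 0.27). The stress-responsive factor ATF3 went from 2.54 and 2.05 FPKM to 17.1 and 14.5 FPKM. ARC had 0.779 and 0.646 FPKM untreated and 7.38 and 7.46 FPKM treated. CYR61, a secreted matrix-associated protein, had 2.63 and 2.34 against 10.5 and 11.8 FPKM, and IER5 5.79 and 6.07 against 20.8 and 31.8 FPKM. The limma adjusted p in the main fit was 0.671 for each of these 7 genes. With a block for the replicate number, EGR1, ATF3, ARC, IER5 and CYR61 passed (limma adjusted p from 5.09e-05 to 0.0179), and FOS and JUN did not. The block fit also called rows that moved in 1 treated library only. RPS10, for example, had 1.39 and 3.02 FPKM untreated and 2.57 and 3596 FPKM treated (limma adjusted p = 9.99e-18). Passing the block fit therefore does not show on its own that both treated libraries changed.

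**Figure D1:**
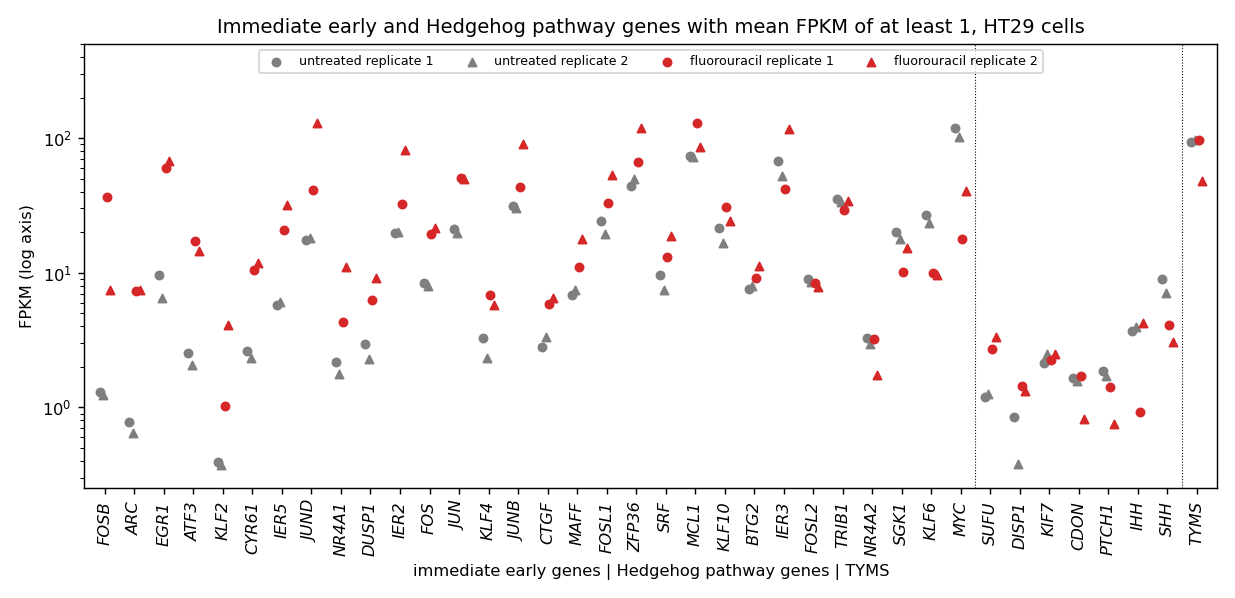
FPKM of each library on a log axis for the 30 tested immediate early genes, the 7 tested Hedgehog pathway genes and TYMS; grey points are untreated and red points treated libraries, circles replicate 1 and triangles replicate 2. In 23 of the 30 immediate early genes both red points lie above both grey points, while MYC and KLF6 have both red points below.

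The 4 immediate early genes with lower values were MYC, KLF6, SGK1 and FOSL2. MYC, which encodes a transcription factor that drives growth and ribosome production, measured 119 and 102 FPKM untreated and 17.9 and 40.4 FPKM treated (log2 change -2.03, SE 0.49, limma adjusted p = 0.671). KLF6, a Krüppel-like factor, had 26.8 and 23.2 FPKM untreated and 9.97 and 9.61 FPKM treated. Without fluorouracil replicate 2, MYC passed the test with a log2 change of -2.62 (limma adjusted p = 0.0465). FOSB, another subunit of AP-1, passed in that fit in the other direction, with a log2 change of 4.74 (limma adjusted p = 0.0399). It had 1.31 and 1.24 FPKM untreated and 36.8 and 7.49 FPKM treated, and its log2 change over all libraries was 3.60 (SE 0.83). With the replicate block, FOSB and MYC passed (limma adjusted p = 5.18e-07 and 0.0467), and KLF6 did not. TYMS, the gene of thymidylate synthase, had overlapping values: 95.3 ± 3.14 FPKM untreated, 96.8 FPKM in fluorouracil replicate 1 and 48.1 FPKM in fluorouracil replicate 2.

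No single gene was called between the conditions. Of 12462 genes, 0 had a limma adjusted p below 0.05, 400 had an unadjusted p below 0.05, and the smallest adjusted p was 0.671. Both treated values lay above both untreated values in 3043 genes (24.4%) and below in 2409 genes (19.3%), where chance gives 16.7% in each direction. The count was 18 without fluorouracil replicate 2 and 8337 without fluorouracil replicate 1, fits in which the lone treated library was assumed to vary like the untreated pair. With 2 libraries against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333.

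The genes with the smallest unadjusted p among those with higher treated values did not pass the adjusted test in the main fit either. Besides EGR1, ATF3, ARC, CYR61 and IER5, they included SERTAD1, a transcriptional coregulator, at 19.0 and 14.8 FPKM untreated and 101 and 182 FPKM treated. HBEGF, a ligand of the epidermal growth factor receptor, was at 2.87 ± 0.0238 and 11.6 ± 0.110 FPKM. IFNL1, a type III interferon, had 0.587 and 0.795 FPKM untreated and 9.74 and 5.16 FPKM treated. The melanocortin receptor gene MC1R had 0.787 and 1.16 against 7.32 and 17.2 FPKM. The remaining genes of this group were VAMP1, with a log2 change of 2.01, and KCNJ14 and RND1, with mean FPKM of 11.5 and 7.99 treated against 2.43 and 1.69 untreated. With the replicate block, each gene named in this paragraph passed (limma adjusted p from 2.98e-05 for MC1R to 0.0485 for VAMP1). That fit also called rows that moved in 1 treated library only.

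The genes with the smallest unadjusted p among those with lower treated values did not pass the adjusted test in the main fit either. With the replicate block, SLITRK6, EREG, EDN1, SNORD20 and LOC101928281 passed (limma adjusted p from 0.000270 to 0.0206), and the others named in this paragraph did not. That fit also called rows that moved in 1 treated library only. EREG, which encodes the epidermal growth factor receptor ligand epiregulin, measured 39.4 and 31.1 FPKM untreated and 8.93 and 5.02 FPKM treated. EDN1, the precursor of the vasoconstrictor endothelin, had 11.4 and 8.82 against 2.22 and 1.23 FPKM. SLITRK6, a transmembrane protein, had 20.2 and 17.6 against 4.32 and 1.88 FPKM. The potassium channel subunit gene KCNE3 was at 17.6 ± 0.838 and 5.32 ± 0.355 FPKM, and the lactate receptor gene HCAR1 at 16.8 ± 0.666 and 5.17 ± 0.602 FPKM. PLK2, a Polo-like kinase, was at 80.2 ± 3.18 and 24.9 ± 4.95 FPKM. LINC00675, ARID5B and LOC101928281 had log2 changes of -1.57, -2.02 and -2.11. The small RNAs SNORD20 and MIR374C were listed at 0 in both treated libraries. SNORD20 had 4.49 and 7.66 FPKM in the untreated libraries and MIR374C 3.08 and 3.89. A 0 in fluorouracil replicate 2 is common among such rows: of 240 small RNA and tRNA rows with at least 1 FPKM in each of the other 3 libraries, 228 were listed at 0 in it. The matching count was 0 in each other library, of 11 to 13 rows. Of 275 such rows with at least 1 FPKM in both untreated libraries, 263 were at 0 in fluorouracil replicate 2 and 20 in fluorouracil replicate 1.

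Of 25 gene lists tested, 9 were called by camera with the preset inter-gene correlation, and none of the 25 was called with an estimated correlation or by fry. Mitosis genes fell as a group: 13 of 20 had lower values in both treated libraries, 0 had higher values, and the mean log2 change was -0.45 (adjusted p = 0.000724; adjusted p = 0.604 with an estimated correlation). The medians were -0.23 in fluorouracil replicate 1 and -0.73 in fluorouracil replicate 2. CCNA2, which encodes cyclin A2, had 68.7 and 64.5 FPKM untreated and 54.4 and 27.3 FPKM treated. TOP2A, a topoisomerase, had 88.0 and 106 against 78.6 and 34.0 FPKM. None of the 20 reached an unadjusted limma p below 0.05. The mean log2 change of the list was -0.20 without fluorouracil replicate 2 and -0.71 without fluorouracil replicate 1, and the list was called in both cases. A fit that leaves 1 library in a group takes its spread from the other group alone. List calls without 1 treated library, here and below, therefore hold no spread between treated libraries.

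Genes of the integrated stress response, which operates through the translation factor eIF2 and the transcription factor ATF4, rose as a group. Of 19 genes, 15 had higher values and 1 had lower values in both treated libraries; the mean log2 change was 0.76 (camera adjusted p = 0.000724; adjusted p = 0.604 with an estimated correlation). Medians were 0.25 and 1.47 in fluorouracil replicates 1 and 2, and 0.23 and 0.58 with the GC and length trend removed, where the mean was 0.46 (adjusted p = 0.000305). The mean was 0.34 without replicate 2 and 1.19 without replicate 1 of the treated libraries, and the list was called in both cases. PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2, was at 29.6 ± 0.837 FPKM untreated and had 100.4 and 82.1 FPKM in the treated libraries; without fluorouracil replicate 2 it passed the limma test with a log2 change of 1.76 (adjusted p = 0.0465). DDIT3, the transcription factor CHOP, had 17.5 and 16.9 against 28.1 and 51.8 FPKM, and CHAC1 had 4.37 and 4.89 against 10.4 and 49.2 FPKM.

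Histone genes rose as a group, with higher values in 10 of 15 tested genes and lower values in 0 (mean log2 change 1.03, camera adjusted p = 0.000724; adjusted p = 0.604 with an estimated correlation). HIST2H2BE measured 6.07 and 4.50 FPKM untreated and 11.5 and 17.2 FPKM treated, and HIST1H2BG 1.94 and 0.918 against 4.29 and 5.29 FPKM. Histone genes occur as near-identical copies, so their single values are uncertain. With the GC and length trend of the libraries removed, the mean log2 change was 0.41 and the call was lost (adjusted p = 0.0877). Without fluorouracil replicate 2 the mean was 0.39 (adjusted p = 0.0161), and without fluorouracil replicate 1 it was 1.66 (adjusted p = 0.00976).

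Wnt targets and intestinal stem cell genes fell as a group, with lower values in 7 of 11 tested genes and higher values in 1 (mean log2 change -0.30, median -0.57, camera adjusted p = 0.00754; adjusted p = 0.604 with an estimated correlation). RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, was at 51.3 ± 0.208 FPKM untreated and 20.7 ± 0.0490 FPKM treated. AXIN2, a negative feedback component of the pathway, had 15.8 and 15.7 against 7.61 and 9.86 FPKM. The transcription factor gene SOX9 was at 27.2 ± 2.51 and 13.7 ± 3.22 FPKM, and the ubiquitin ligase gene ZNRF3 had 11.6 and 9.36 against 7.02 and 5.66 FPKM. The list was not called without fluorouracil replicate 1, where the mean log2 change was 0.02 (adjusted p = 0.464), nor without untreated replicate 1 (-0.32, adjusted p = 0.0863) or untreated replicate 2 (-0.27, adjusted p = 0.103). Without fluorouracil replicate 2 the mean was -0.62 (adjusted p = 2.68e-06). With the GC and length trend removed it was -0.56 (adjusted p = 0.000335), and after quantile normalization -0.45 (adjusted p = 0.00426).

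Cholesterol synthesis genes rose as a group, with higher values in 8 of 20 genes and lower values in 0 (mean log2 change 0.48, camera adjusted p = 0.0206, and 0.604 with an estimated correlation). Of 15 reference genes such as ACTB and GAPDH, a list that was not called (camera adjusted p = 0.199), 6 had higher and 2 lower values. Medians in fluorouracil replicates 1 and 2 were 0.0068 and 0.72 for the reference genes, and 0.26 and 0.79 for cholesterol synthesis genes. INSIG1, a sterol-regulated membrane protein, was at 46.3 ± 5.52 and 104 ± 0.878 FPKM. With the GC and length trend removed, the cholesterol list was called with a mean log2 change of 0.35 (camera adjusted p = 0.000305). Its mean was 0.34 without fluorouracil replicate 2. The cholesterol call was lost after quantile normalization (mean log2 change 0.25, adjusted p = 0.125), without untreated replicate 1 (0.43, adjusted p = 0.137) and without fluorouracil replicate 1 (0.62, adjusted p = 0.387). Ribosome biogenesis genes fell as a group, with lower values in 11 of 28 genes and higher values in 4 (mean log2 change -0.25, adjusted p = 0.0283; adjusted p = 0.604 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, had 16.6 and 15.9 against 10.5 and 6.46 FPKM. The ribosome biogenesis call was lost without untreated replicate 1 (mean log2 change -0.25, adjusted p = 0.0581), untreated replicate 2 (-0.24, adjusted p = 0.0517) or fluorouracil replicate 1 (-0.34, adjusted p = 0.262). The list was called without fluorouracil replicate 2, with a mean of -0.15 (adjusted p = 0.00223), after quantile normalization (-0.48, adjusted p = 0.00140) and with the GC and length trend removed (-0.40, adjusted p = 1.80e-05).

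In 2 called lists the median change lay near 0 in fluorouracil replicate 1 and above 1 in replicate 2. The median log2 change of 40 ribosomal protein genes was 0.01 in replicate 1 and 1.13 in replicate 2 (camera adjusted p = 0.00154; adjusted p = 0.686 with an estimated correlation). Their mean log2 change was 0.58, but -0.0087 after quantile normalization and 0.28 with the GC and length trend removed (adjusted p = 0.0423). RPS24, for example, had 261 and 221 FPKM untreated and 235 and 4637 FPKM treated. The 20 interferon response genes had medians of -0.02 and 1.63 (adjusted p = 0.00951; adjusted p = 0.685 with an estimated correlation), and a mean of 0.91 that was 0.60 after quantile normalization (adjusted p = 0.0257). ISG20, an exonuclease gene of this list, was at 3.94 ± 0.928 FPKM untreated and had 6.46 and 70.7 FPKM in the treated libraries. Without fluorouracil replicate 2, the mean log2 change was 0.0106 for ribosomal proteins (adjusted p = 0.944) and 0.14 for interferon response genes (adjusted p = 0.754); without fluorouracil replicate 1 these means were 1.15 and 1.68. Both calls were also lost without untreated replicate 2 (adjusted p = 0.0517 and 0.0685; mean log2 change 0.52 and 0.58).

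**Figure D2:**
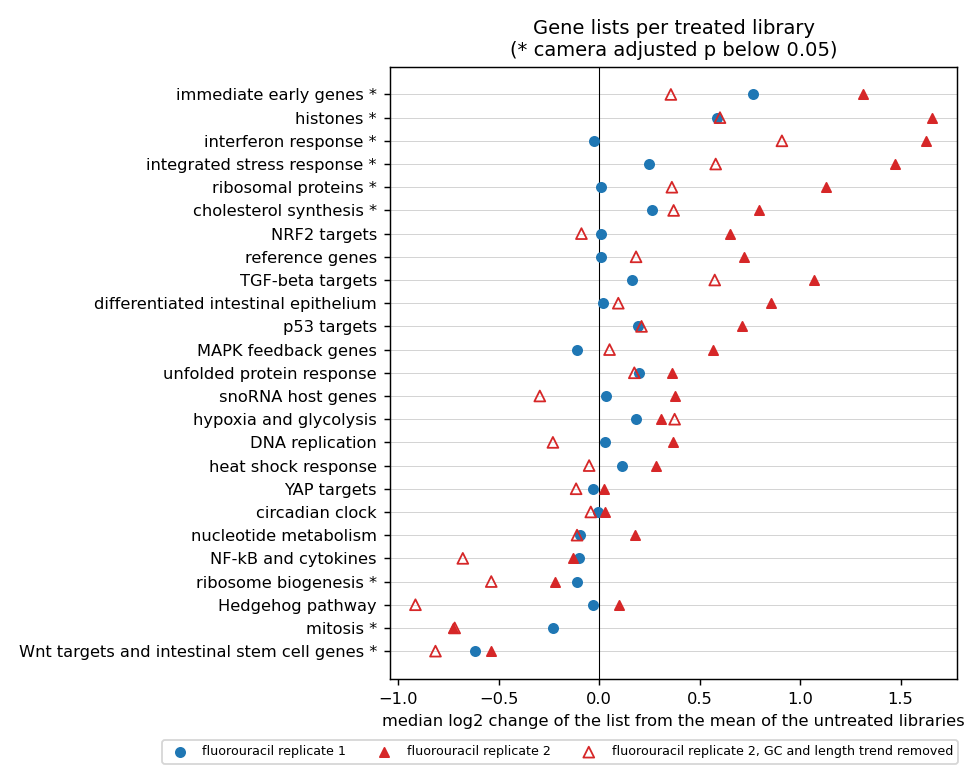
Median log2 change of each of the 25 tested gene lists from the mean of the untreated libraries, for fluorouracil replicate 1 (blue circles), fluorouracil replicate 2 (filled triangles) and the latter after the GC and length trend was removed (open triangles, protein-coding members); asterisks mark the 9 lists called by camera. Immediate early genes lie at 0.77 and 1.31 in the 2 libraries, ribosomal proteins at 0.01 and 1.13; after quantile normalization the mean of the ribosomal proteins is -0.0087.

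The other 16 lists were not called, with camera adjusted p from 0.103 for TGF-beta targets to 0.705 for MAPK feedback genes. Among them were p53 targets (10 of 24 higher, 3 lower, adjusted p = 0.138) and DNA replication genes (6 of 29 higher, 4 lower, adjusted p = 0.577). The nucleotide metabolism list, which holds TYMS, had 2 of 23 genes higher and 8 lower (adjusted p = 0.620). Its mean log2 change of 0.14 and the lower direction of its test differed in sign, as did the mean of -0.02 and median of 0.35 of MAPK feedback genes. Notch targets and non-epithelial markers had 4 tested members each, below the minimum of 5. None of the 13 symbols of the mitochondrial transcript list, which carry the prefix MT-, were matched to the rows of the table used here. This does not show that mitochondrial transcripts are absent from it under other symbols.

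Fluorouracil replicate 2 stood apart from the other 3 libraries. Across the tested genes, its log2 values had a Pearson r of 0.704 to 0.716 with the other libraries, which among themselves had an r of 0.960 to 0.980. Across 10957 protein-coding genes, its deviation from the mean of the others had a Spearman rho of 0.702 with GC content and -0.421 with transcript length. The same values lay between -0.0318 and 0.0302 for GC content and between -0.0925 and 0.148 for length in the other 3 libraries, each set against the remaining ones without fluorouracil replicate 2. Set against the median of all 3 others, with fluorouracil replicate 2 among them, untreated replicate 2 reached -0.320 with GC content and 0.280 with length. Genes are not independent replicates, and these correlations describe the libraries. With this trend removed, immediate early genes had a mean log2 change of 0.67 (camera adjusted p = 1.93e-05), and 0 genes were called by limma, with 870 at an unadjusted p below 0.05.

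**Figure D3:**
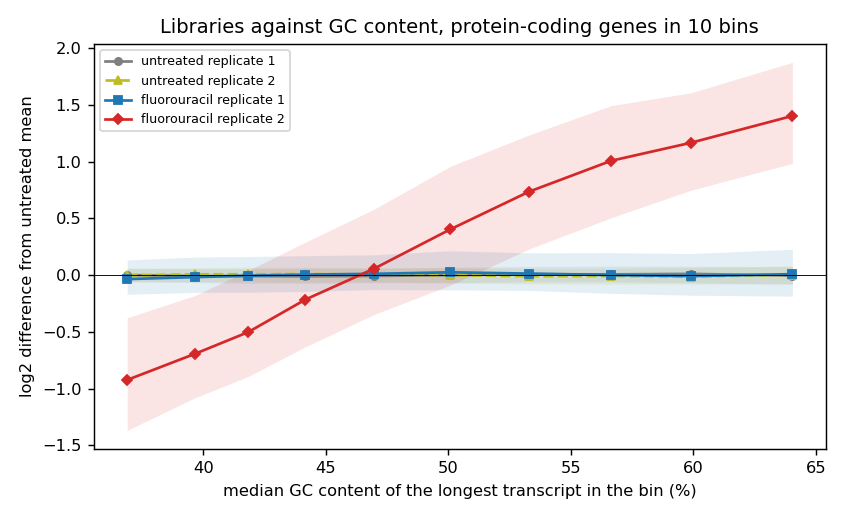
Median log2 difference of each library from the mean of the untreated libraries in 10 bins of protein-coding genes by GC content of the longest transcript, with shaded bands from the 25th to the 75th percentile of genes. The line of fluorouracil replicate 2 climbs with GC content (Spearman rho 0.702 across genes), and the lines of the other 3 libraries stay near 0.

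The treated libraries were also set against separate untreated libraries, in a comparison chosen after the values were seen, so that no library entered both sides. With the trend removed, 141 protein-coding genes were at least 2-fold lower in fluorouracil replicate 1 than in untreated replicate 1. Of these, 66 (46.8%) were also at least 2-fold lower in fluorouracil replicate 2 than in untreated replicate 2, against 5.90% of all protein-coding genes. For at least 2-fold higher genes the values were 115 of 271 (42.4%) against 10.6%. The filter took the mean of all 4 libraries, so genes with higher values that were below 1 FPKM untreated entered only through their treated values. No conclusion is therefore drawn from the shares of higher genes. With the untreated libraries exchanged, the shares were 56.4% against 6.56% and 41.6% against 10.5%. In the values as deposited, 47 of 136 lower genes (34.6%) were also lower in fluorouracil replicate 2, against 12.7% of all, and 187 of 281 higher genes (66.5%) were also higher, against 27.9%. With the untreated libraries exchanged, these shares were 43.0% against 12.5% and 63.4% against 27.6%.

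**Figure D4:**
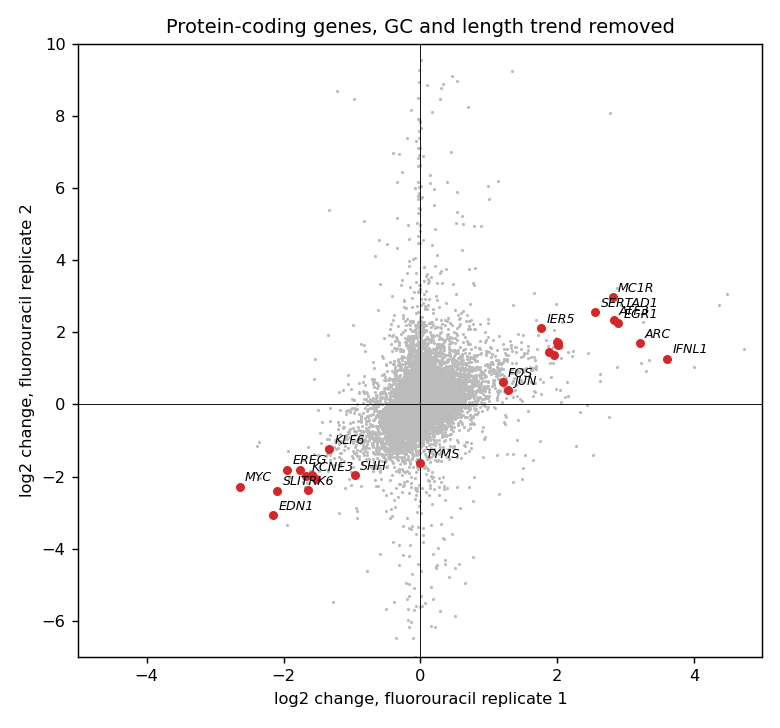
Log2 change of protein-coding genes in fluorouracil replicate 1 (x axis) and fluorouracil replicate 2 (y axis) from the mean of the untreated libraries, with the GC and length trend removed. In grey, 10943 genes are drawn, and 14 lie outside the axes. Red points are SHH, FOS, EGR1, JUN, MYC, TYMS and the genes of smallest unadjusted p with non-overlapping groups. Other genes named in the text are grey. MYC lies at -2.64 and -2.28 and EGR1 at 2.89 and 2.25 in the 2 libraries.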

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

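The runs on protein-coding genes, with the GC and length trend removed and without the shifted rows were chosen after seeing the data; all others were planned. The count of called genes was 0 in the main analysis and stayed 0 in all alternatives except these: 339 with the replicate block (78 higher, 261 lower; 195 of the lower were at 0 in fluorouracil replicate 2, and 149 were small RNA or tRNA rows), and 0 to 8337 when each library was left out in turn, of which 8337 without fluorouracil replicate 1 and 18 without fluorouracil replicate 2. Of those 18, 10 were small RNA or tRNA rows. Within-group deviations of same-numbered libraries had an r of -0.0479 across genes. This r cannot show whether the numbers pair the libraries, because the distance of fluorouracil replicate 2 from the others enters the treated deviations. Its SD of log2 differences from untreated replicate 1 was 3.02 times that of fluorouracil replicate 1. The labels do not say whether same-numbered libraries belong together, and the main fit had no replicate block. Quantile normalization moved the median log2 change of all genes from 0.10 by -0.12. The number of called lists was 9, 6 to 9 when each library was left out, 7 after quantile normalization and 6 with the replicate block, where Wnt targets (adjusted p = 0.279), cholesterol synthesis (0.177) and ribosome biogenesis (0.240) were no longer called; it was 0 with an estimated inter-gene correlation and 0 with fry, tests in which the mean log2 change of immediate early genes is 1.07 as before (adjusted p = 0.604 and 0.148). In the other 10 alternatives run for lists, immediate early genes, mitosis and the integrated stress response were called each time. The mitosis call lay near the threshold with the replicate block (camera adjusted p = 0.0470). Alternatives that leave out a library hold no spread within the group that loses it. The mean log2 change of immediate early genes lay between 0.89 and 1.25 when each library was left out. That of ribosomal proteins was reversed in sign at -0.0087 after quantile normalization, and its test turned direction without fluorouracil replicate 2, where the mean was 0.0106 (0.0106 to 1.15 when each library was left out). Why these values moved was not tested. TYMS and RPS24 changed sign without fluorouracil replicate 2, to 0.02 and -0.03. For single genes, 816 pairs of gene and setting kept their side of the threshold and 84 passed it only in the alternative; for lists the values were 257 and 5, with 34 losing the call. Directions of genes and lists that passed in neither setting were not compared in these counts. With the GC and length trend removed, 10 lists were called, 8 of them shared with the main analysis; the histones were lost, and NF-kB genes (lower) and unfolded protein response genes (higher) were gained. The estimated correlation and fry were not run in that setting; in the main one they gave an adjusted p = 0.604 and 0.342 for NF-kB genes and an adjusted p = 0.604 and 0.148 for the unfolded protein response. Tests for counts were not run, because the table holds FPKM.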

Other observations

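The tests of GC content, gene models and handling, the count of small RNA rows at 0, and the trend-corrected values of lists and genes, were chosen only after the results were seen, as was leaving fluorouracil replicate 2 out of the reference for the GC trend of the other libraries; the test of AU-rich motifs was written down before its result. The test of intestinal genes was written down before its result for any other cells, and narrowed to cells that are not intestinal epithelium afterwards; the test of another intestinal line was added afterwards. The genes named in the next paragraph were chosen after their values were seen.

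Of 16 tested NF-kB and cytokine genes, 4 had higher values in both treated libraries, 7 had lower values and 5 overlapped. Among those with lower values, IL8 measured 28.1 and 13.4 FPKM untreated and 6.09 and 2.80 FPKM treated, CXCL1 13.8 and 11.1 against 5.51 and 2.22 FPKM, and CXCL3 5.82 and 3.58 against 1.10 and 1.06 FPKM. The list was not called in the main analysis (mean log2 change -0.31, camera adjusted p = 0.135; adjusted p = 0.604 with an estimated correlation and 0.342 by fry). The mean was -0.17 without untreated replicate 1 (adjusted p = 0.375) and -0.44 without untreated replicate 2, where the list was called (adjusted p = 0.0457). It was also called as lower with the GC and length trend removed (mean log2 change -0.60, camera adjusted p = 0.00484), a setting in which the other tests were not run. Outside this list, the transcription factor gene KLF5 was at 118 ± 0.888 against 47.1 ± 4.11 FPKM (SD), and ETS2 had 77.9 and 82.9 against 28.8 and 34.9 FPKM. BMP4, a secreted growth factor, had 178 and 149 against 32.4 and 75.5 FPKM. On the higher side, the p53 target CDKN1A, a cell cycle inhibitor, had 14.1 and 10.9 against 29.4 and 66.1 FPKM, and SESN2 had 3.03 and 3.61 against 8.89 and 19.3 FPKM. GADD45B had 2.92 and 1.19 against 18.3 and 15.7 FPKM. None of these 9 genes passed the adjusted limma test over all genes in the main fit (adjusted p = 0.671). With the replicate block, IL8 (limma adjusted p = 0.00659), SESN2 (0.0327) and GADD45B (1.41e-05) passed and the others did not. That fit also called rows that moved in 1 treated library only.

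Fluorouracil replicate 2 stood apart from the other 3 libraries, with an SD of log2 differences from untreated replicate 1 that was 3.02 times that of fluorouracil replicate 1. Replacement by cells that are not intestinal epithelium is argued against. Of 8 differentiated intestinal epithelium genes with at least 5 FPKM in the other libraries, 0 were below 1 FPKM in fluorouracil replicate 2. Another intestinal line, or a mixture of cells, was tested by a count. Read-through rows aside, 34 protein-coding rows had at least 5 FPKM in fluorouracil replicate 2 and under 0.1 in each other library. Other gene models would give such rows as well, so their count cannot tell these explanations apart. The rows include EIF4A1 and MRPS24, each at 0 in every other library and at 513 and 221 FPKM in fluorouracil replicate 2. What the identity of these genes speaks for was not tested. A trend with GC content (Spearman rho 0.702) may account for part of the distance but not for the whole, since the highest Pearson r with another library was 0.865 once it was removed, against at least 0.975 among the others. FPKM computed with other gene models or lengths are a candidate explanation for the rest: 0.289% of its low values shared 1 ratio to untreated replicate 1, against at least 18.5% in the other libraries, and 14 read-through rows had at least 5 FPKM in it alone, against 0 in each other library. In it, 228 of 240 small RNA and tRNA rows with at least 1 FPKM in each other library were at 0, against 0 in each other library; a different library preparation or annotation stays open for these, and no biological explanation was tested, since the other library of its group did not show the pattern.

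Immediate early genes were higher in both treated libraries. The GC and length trend of fluorouracil replicate 2 is argued against as the whole cause. The list was called by camera after the trend was removed (adjusted p = 1.93e-05). It was also called without that library, with a mean log2 change of 0.89, in a fit that holds no spread between treated libraries. Removing the trend lowered the mean log2 change from 1.07 to 0.67 and the median of fluorouracil replicate 2 from 1.31 to 0.36, and before removal the list was not called with an estimated correlation (adjusted p = 0.604) or by fry (adjusted p = 0.148). Handling of the treated cultures cannot be told apart from the drug, because the labels name 0 libraries handled with vehicle. A response to fluorouracil, the difference the design names, stays open beside it.

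With the GC and length trend removed, 65 protein-coding genes were at least 2-fold lower in both treated libraries and 116 at least 2-fold higher, against the same untreated libraries. The filter took the mean of all 4 libraries, so many of the higher genes, with untreated values below 1 FPKM, entered only through their treated values. HYPK, for example, was at 0 in both untreated libraries and at 0.157 and 72.5 FPKM in fluorouracil replicates 1 and 2. Such genes were not counted, so no conclusion is drawn from the excess of higher genes over the simulations given next. The lower lists held 110 genes in fluorouracil replicate 1 and 671 in replicate 2, and the higher lists 245 and 1116. Independent lists of these sizes would overlap in 6.74 lower and 24.95 higher genes. In 100 simulations the changes were shuffled among genes of like expression and the controls were kept shared. They gave means of 10.6 lower and 91.6 higher genes, with highest values of 25 and 109. The lower genes may be rich in unstable transcripts: 33 of 65 (50.8%) had the AU-rich motif TATTTAT in the 3' UTR, against a mean of 33.1% in 10000 random sets matched on length and GC content of the 3' UTR (one-sided permutation p = 6e-04). The motif was not peculiar to lower genes, since 35.3% of the higher genes had it, against 23.4% in their matched sets (one-sided permutation p = 0.0012). Of all 10949 genes searched, 34.2% had the motif, below the share of the lower genes and near that of the higher ones. Transcript stability was not measured, and random sets were not matched on expression.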
